A study of Rattus norvegicus with 12 samples.

How the data were processed

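Small RNA was sequenced from 12 samples of aorta from female rats of the SHR strain, 6 given saline (control) and 6 labelled EWH. Per the labels' protocols, total RNA was extracted with Trizol, adaptors were ligated to both ends, and after RT-PCR a gel band holding inserts of 15 to 35 nt was taken. Per the submitters' processing notes the genome build was rn6. The aligner, the counting tool, the miRNA annotation, the strand setting and the reads that make up each library's total are not given in the sources used here.

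The authors deposited 1 table of 641 mature rat miRNAs in 12 libraries, whose values, from their own steps, are in reads-per-million (RPM) units: each is a whole number of reads divided by a total of its library, on a per-million scale. The table is named for another unit, TPM, but no length term was found, since the smallest step was the same for all miRNAs of a library. Dividing by that step gave whole reads for 100% of the values within a tolerance of 0.01 read. The totals behind the values were 23887799 to 24772944 reads, and reads in the listed miRNAs were 18579313 to 19805795, or 76.4% to 80.6% of those totals. A read was worth 0.0404 to 0.0419 rpm, and a floor of 3 reads, for counting error only, lay at 0.121 to 0.126 rpm. Reads carried no molecular identifiers in the sources used here, so they are not independent molecules. Between 481 and 549 miRNAs had a read in a library. Replicates were compared by chi-square on recovered reads, over miRNAs with at least 20 reads.

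Each column was mapped to its sample through the sample's own description, and no column was left over. Groups came from the treatment label. Before the data were examined, the tests, the 17 miRNA lists, the rule for named miRNAs and the alternatives were fixed, apart from those stated to be added later. MiRNAs with at least 1 rpm in at least 6 of 12 libraries were tested (303 of 641). Values were taken as log2(rpm + 1), so a fold change is on that scale and understates the change of low miRNAs. Groups were compared with limma 3.58.1 (trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05.

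The lists were contractile smooth muscle, proliferative smooth muscle, endothelial, angiotensin and blood pressure, inflammation, hypoxia and oxidative stress, miR-29 and antifibrotic, profibrotic, let-7 family, miR-17-92 and paralogous clusters, Dlk1-Dio3 imprinted cluster, and markers of erythrocytes, leukocytes, skeletal and cardiac muscle, adipocytes, neurons and glia, and epithelium and hepatocytes. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other tested miRNAs; an estimated correlation and fry, which tests whether a list moves one way without comparing it with other miRNAs, were alternatives. Both arms and all copies of each hairpin counted as list members, and lists could share members. Members were also adjusted over the list alone. For 67 hairpins with both arms tested, log2((5p + 1)/(3p + 1)) was compared with limma. Whole profiles were compared by permutational multivariate analysis of variance on Euclidean distances, and 4 measures of composition and the mean log2 value of each list by two-sided exact permutation over all 924 splits.

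The rule named the 12 miRNAs with the highest and the 12 with the lowest moderated t among those averaging at least 10 rpm (since fewer than 20 passed), the 10 most abundant, up to 3 most abundant tested members of each list, and the 3 arm ratios with the smallest p. Not all of the list members named by the rule are printed in the text. Other names were chosen after their values were seen. RefSeq's gene table was of another assembly (GRCr8) than the data, so it served only for names and neighbours; 632 of 641 identifiers matched, and 1 listed entry joins 2 mature miRNAs.

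Alternatives were no filter, a filter at 10 rpm, pseudocounts of 0.1 and 5, median-of-ratios scaling, quantile normalization, limma without trend and with robust variances, the replicate number as a block, each library left out in turn, and, on the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. After seeing the data, fits without EWH 3 and 4 together, without these and control 1, and edgeR with libraries left out were added. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

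The procedures were tested on simulated counts with the real means and library sizes, 6 against 6, where 311 miRNAs passed the filter. Limma recovered 58.8% of 51 miRNAs changed 2-fold and 89.8% of 49 changed 4-fold with 4 false calls, edgeR 60.8% and 91.8% with 5, and DESeq2 66.7% and 98.0% with 5. With no miRNA changed they made 2, 1 and 2 calls. Of 15 arm ratios changed 4-fold among 70 tested, 73.3% were recovered with 1 false call, and camera called the 1 list shifted 2-fold and no other. Simulated miRNAs varied independently of each other, while members of real lists were correlated (estimated correlation 0.935 in the Dlk1-Dio3 list). The simulation therefore does not show how many false calls camera makes on the real lists. The simulated data also held no library set apart in many miRNAs at once. With 51 and 49 of 311 miRNAs changed, the adjusted threshold was easier to pass than with few changes. The recovered shares therefore need not hold for the real data.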

Results

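MicroRNAs were measured by small RNA sequencing in aortas of the spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, from females. A control group of 6 samples had received saline and a group of 6 samples carried the treatment label EWH; the series title names egg white-derived peptides and blood pressure. The question put by the design was which aortic miRNAs differ between the 2 groups. The deposited reads-per-million (rpm) values of a library rested on totals of 23887799 (EWH 6) to 24772944 (EWH 2) reads, of which 76.4% to 80.6% fell in the 641 listed miRNAs. At that depth 1 read was worth 0.0404 to 0.0419 rpm, and a listed 0 allowed at most 0.121 to 0.126 rpm, the value of 3 reads, which covers counting error only. Nothing in the labels says that samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. No pair among the 30 pairs of libraries of one group agreed within sampling noise (chi-square per degree of freedom 119 to 3184), so none was taken as a repeat deposit of one library. Identifiers carry the rat prefix rno-, which is left out here. Reads shared by near-identical miRNAs or by overlapping hairpins could have gone to either, since neither strand handling nor multiple mapping is given in the sources used here. By RefSeq's table for the assembly GRCr8, 18 of the 65 miRNAs named by rule have a hairpin that overlaps another miRNA hairpin. Among them are miR-409b, miR-9a-5p, miR-1-3p, both miR-338 arms, miR-382-5p, miR-434-5p and miR-3596a, whose hairpin overlaps that of let-7a-2. Near-identical mature miRNAs were not counted, so other named miRNAs may share reads too.

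In both groups the most abundant miRNA was miR-143-3p, which is abundant in contractile smooth muscle. It held 50.5% ± 3.43 (SD, n = 6) of the listed reads in control and 48.3% ± 4.22 (SD, n = 6) in EWH. Next in mean abundance came miR-26a-5p (105195 rpm), miR-99a-5p (36693 rpm), let-7f-5p (28990 rpm), let-7c-5p (26601 rpm), let-7i-5p (24165 rpm), miR-10a-5p (21438 rpm), let-7a-5p (14790 rpm), miR-27b-3p (11391 rpm) and let-7g-5p (8108 rpm). The 10 most abundant miRNAs of a library held 84.4% ± 1.41 of its listed reads in control and 85.1% ± 1.25 in EWH (SD, n = 6 each). Libraries held 298 ± 8.40 miRNAs at 1 rpm or more in control and 310 ± 24 in EWH (SD, n = 6 each). The median log2(rpm + 1) of the tested miRNAs was 4.31 ± 0.18 in control and 4.35 ± 0.36 in EWH (SD, n = 6 each). None of the 4 measures of composition passed a two-sided exact permutation test over 924 splits (Benjamini-Hochberg adjusted p 0.502 for the first 3 and 0.835 for the median).

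Among the miRNAs with the highest moderated t, at higher means in EWH, were members of the Dlk1-Dio3 imprinted region and miRNAs known from nervous tissue. MiR-409b, from the Dlk1-Dio3 region, averaged 16.3 ± 7.06 rpm in control and 125 ± 130 rpm in EWH (SD, n = 6 each), and each EWH library lay above each control. The margin was narrow, with the highest control at 28.2 rpm and the lowest EWH library at 28.6 rpm. MiR-9a-5p, abundant in neural cells, averaged 64.2 ± 21.8 rpm against 250 ± 175 rpm, and miR-204-5p averaged 97.2 ± 34.5 rpm against 289 ± 192 rpm. In the other direction miR-27a-5p averaged 44.7 ± 3.30 rpm in control and 25.8 ± 7.60 rpm in EWH, and miR-20a-5p, from the growth-promoting miR-17-92 cluster, averaged 29.4 ± 25.8 rpm and 8.10 ± 2.07 rpm (SD, n = 6 each). For both of these each EWH library lay below each control. Control 6 read 78.9 rpm and control 5 37.0 rpm in miR-20a-5p, the other controls at most 17.4 rpm, and the control mean without control 6 was 19.5 rpm. Controls 5 and 6 also read 176 and 501 rpm in the epithelial miR-200b-3p (named after its values were seen), against at most 58.6 rpm elsewhere.

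Of 303 tested miRNAs, none passed limma at a Benjamini-Hochberg adjusted p under 0.05. The smallest limma adjusted p was 0.128 with Benjamini-Hochberg adjustment, and 29 miRNAs lay under 0.15. At an unadjusted limma p under 0.05 there were 70 miRNAs, 46 higher and 24 lower in EWH. With a library left out this count ran from 43 (29 higher and 14 lower, without EWH 3) to 72 (without control 3). On the whole reads recovered from the values, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 40 miRNAs, 34 higher and 6 lower, with 79 at an unadjusted p under 0.05. DESeq2 called 63, 46 higher and 17 lower, and all 40 of the edgeR calls were among them. The edgeR count fell to 0 without control 1, 4, 5 or 6, or without EWH 3 or 4, and the limma count was 24 without EWH 2, 1 without EWH 4 (miR-27a-5p) and 8 after quantile normalization. EdgeR called 0 and limma 1 (miR-27a-5p) without EWH 3 and 4 together, a choice made after seeing the data. Groups did not overlap for 5 tested miRNAs, miR-409b above and miR-27a-5p, miR-20a-5p, miR-140-3p and miR-186-5p below the controls, or 1.65% of the tested, where chance gives 0.216%.

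The 12 miRNAs with the highest moderated t among those averaging at least 10 rpm included 5 of the Dlk1-Dio3 list and 3 of the neuron and glia list. The log2 fold change on the log2(rpm + 1) scale was 2.32 (SE 0.59) for miR-409b, 2.08 (SE 0.61) for miR-323-3p, 1.82 (SE 0.60) for miR-433-3p, 1.68 (SE 0.55) for miR-382-5p and 1.58 (SE 0.54) for miR-434-5p. It was 1.67 (SE 0.46) for miR-9a-5p, 1.49 (SE 0.47) for miR-338-5p and 1.47 (SE 0.47) for miR-338-3p, the latter pair from a hairpin inside Aatk that is known from myelinating glia. For the others it was 1.38 (SE 0.40) for miR-204-5p, 1.14 (SE 0.33) for the muscle miRNA miR-1-3p, 0.47 (SE 0.14) for miR-3596a and 0.24 (SE 0.07) for let-7i-5p. All 12 had limma adjusted p (Benjamini-Hochberg) between 0.128 and 0.138, and edgeR called 11 of them at adjusted p = 0.031 with Benjamini-Hochberg adjustment, all but miR-1-3p (0.059). EWH 3 and EWH 4 lay highest of all libraries in miR-409b, at 213 and 351 rpm against at most 80.8 rpm elsewhere. In miR-9a-5p they also lay highest, at 436 and 490 rpm against at most 214 rpm. Without EWH 4 the EWH mean was 80.0 in place of 125 rpm for miR-409b, 17.8 in place of 28.1 rpm for miR-323-3p and 11.1 in place of 18.6 rpm for miR-433-3p. It was 17.3 in place of 26.2 rpm for miR-382-5p and 19.4 in place of 32.1 rpm for miR-434-5p.

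**Figure D1:**
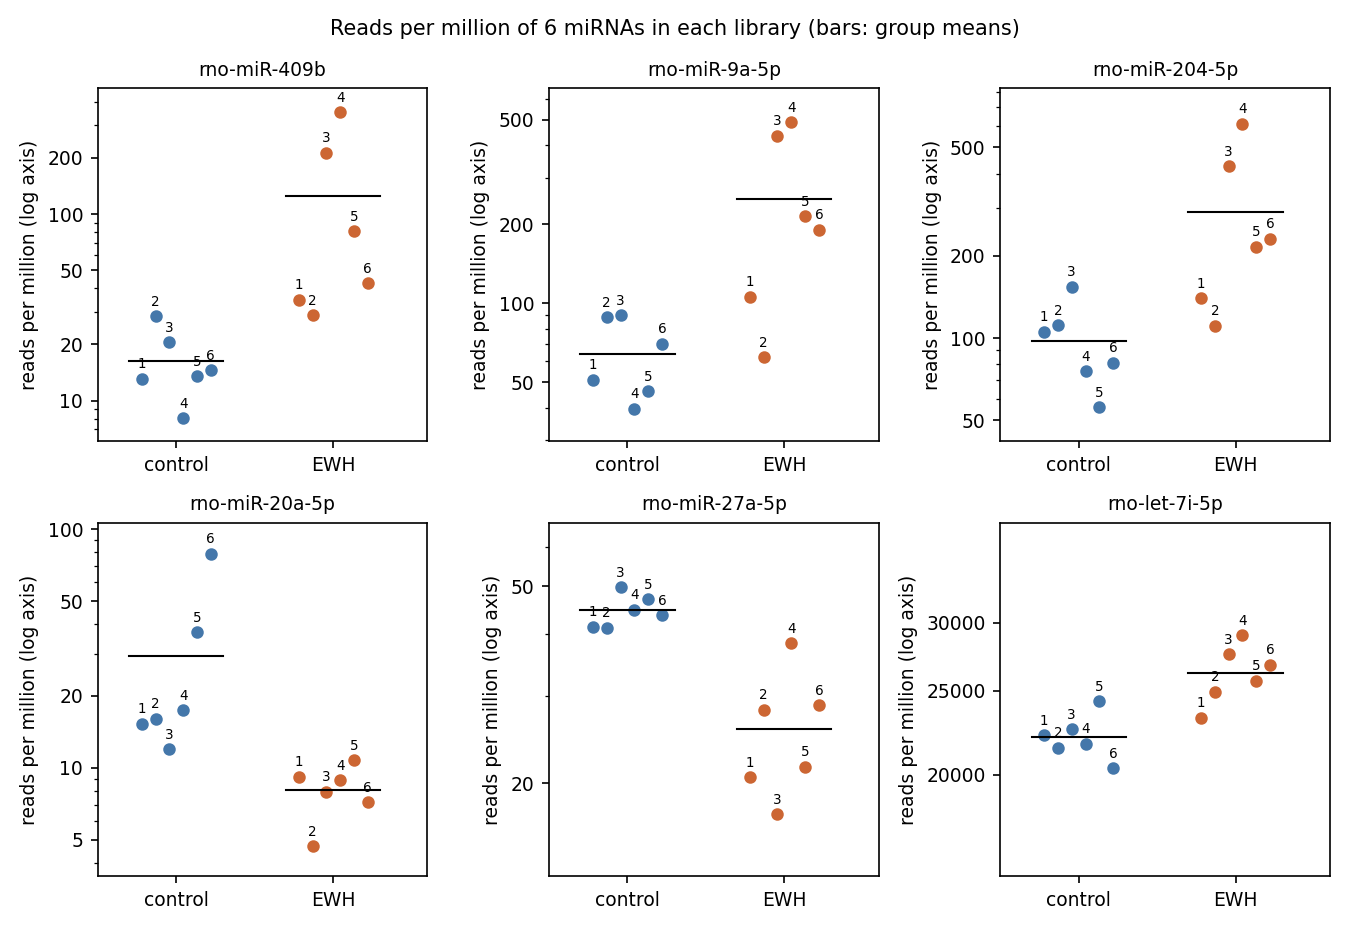
Abundance in rpm (log axis) of 6 miRNAs in each library, control in blue and EWH in orange, with replicate numbers beside the points and bars at the group means. EWH 3 and 4 stand highest for miR-409b, miR-9a-5p and miR-204-5p, while for miR-20a-5p (EWH mean 8.10 rpm) and miR-27a-5p (EWH mean 25.8 rpm) each EWH library lies below each control.

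The 12 with the lowest moderated t were led by miR-27a-5p, the passenger arm of a hairpin clustered with miR-23a and miR-24-2, at −0.81 (SE 0.17) log2. MiR-140-3p followed at −0.55 (SE 0.13), then miR-20a-5p at −1.45 (SE 0.40), miR-22-3p at −0.27 (SE 0.09), miR-186-5p at −0.22 (SE 0.08) and miR-93-5p at −0.69 (SE 0.26). The remaining 6 were miR-31a-5p (−0.37), miR-125b-1-3p (−0.30), the antifibrotic miR-29a-3p (−0.31), miR-148a-3p (−0.44), miR-339-5p (−0.40) and miR-21-5p (−0.34), an miRNA raised in injured vessels. Limma adjusted p (Benjamini-Hochberg) for the 12 ran from 0.128 to 0.171, and edgeR called 2 of them, miR-27a-5p and miR-20a-5p, each at Benjamini-Hochberg adjusted p = 0.031.

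The Dlk1-Dio3 imprinted cluster, a maternally expressed run of miRNA hairpins active in embryonic and neural tissue, had the smallest camera p of the 17 fixed lists. All 26 of its tested members had higher means in EWH, with a median log2 fold change of 1.22, or 2.33-fold. RefSeq's gene order in GRCr8 puts 28 tested miRNAs between Dlk1 and Dio3, these 26 and 2 outside the list, miR-1247-5p at log2 −0.01 and miR-3543 at 1.24 (named after their values were seen). The hairpin of miR-3543 overlaps that of miR-434, a member of the list, so it may share reads and is not a separate observation. The list's most abundant member miR-127-3p averaged 51.7 ± 25.9 rpm in control and 205 ± 222 rpm in EWH, and miR-379-5p averaged 22.6 ± 8.30 rpm and 65.2 ± 60.3 rpm (SD, n = 6 each). EWH 4 read 620 rpm in miR-127-3p, and without it the EWH means were 122 and 42.9 rpm; EWH 1, 2 and 6 (61.4, 51.9 and 79.6 rpm) lay within the controls' 24.9 to 88.0 rpm. None of the 26 passed limma over all tested miRNAs, 24 passed when adjusted over the list alone, and edgeR called 19 over all. Limma's camera with a preset correlation of 0.01 placed the list above the other miRNAs at Benjamini-Hochberg adjusted p = 8.7e-17, which was adjusted p = 0.672 with an estimated correlation, the members being correlated across libraries (estimated correlation 0.935). The mean log2 value of the list was 2.05 ± 0.40 in control and 3.35 ± 1.13 in EWH (SD, n = 6 each; exact permutation p = 0.0173, adjusted p = 0.104 by Benjamini-Hochberg over the 17 lists), with 4 of 6 EWH libraries above the highest control. Its count adjusted over the list alone was 0 without control 1, 4 or 6 or EWH 3, 12 without EWH 4 and 1 of 21 without EWH 3 and 4 together, where the median was 0.66. It was also 0 of 82 with no filter on low values, where 78 were higher with a median of 0.43, and 6 of 6 at a filter of 10 rpm. At a pseudocount of 5 the median was 0.73.

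The neuron and glia list had a median log2 fold change of 1.24, with 8 of 10 tested members higher in EWH. Its most abundant member miR-128-3p did not follow, at 770 ± 264 rpm in control and 683 ± 126 rpm in EWH, and miR-218a-5p read 442 ± 114 and 581 ± 301 rpm (SD, n = 6 each). None of its members passed limma over all tested miRNAs, 3 passed when adjusted over the list alone (miR-9a-5p, miR-338-5p and miR-338-3p), and edgeR called 4 over all. Camera gave adjusted p = 0.0067 (limma, Benjamini-Hochberg), and adjusted p = 0.672 with an estimated correlation. The count adjusted over the list alone was 0 without control 4 or 5, EWH 3, 4 or 5, or with no filter on low values, and 6 without EWH 1 or 2 and under median-of-ratios scaling or quantile normalization. The mean log2 value of the list was 4.81 ± 0.38 in control and 5.83 ± 0.997 in EWH (SD, n = 6 each; exact permutation p = 0.0346, adjusted p = 0.104 by Benjamini-Hochberg). The median was 0.70, with 6 of 10 members higher, without EWH 3 and 4 together, and 0.18, with 18 of 24 higher, with no filter on low values. Beside both lists, EWH 3 and EWH 4 lay apart from all other libraries on the first principal component of the profiles (46.3% of the variance), at 11.97 and 16.2 where the others lay between −7.94 and 4.94.

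**Figure D2:**
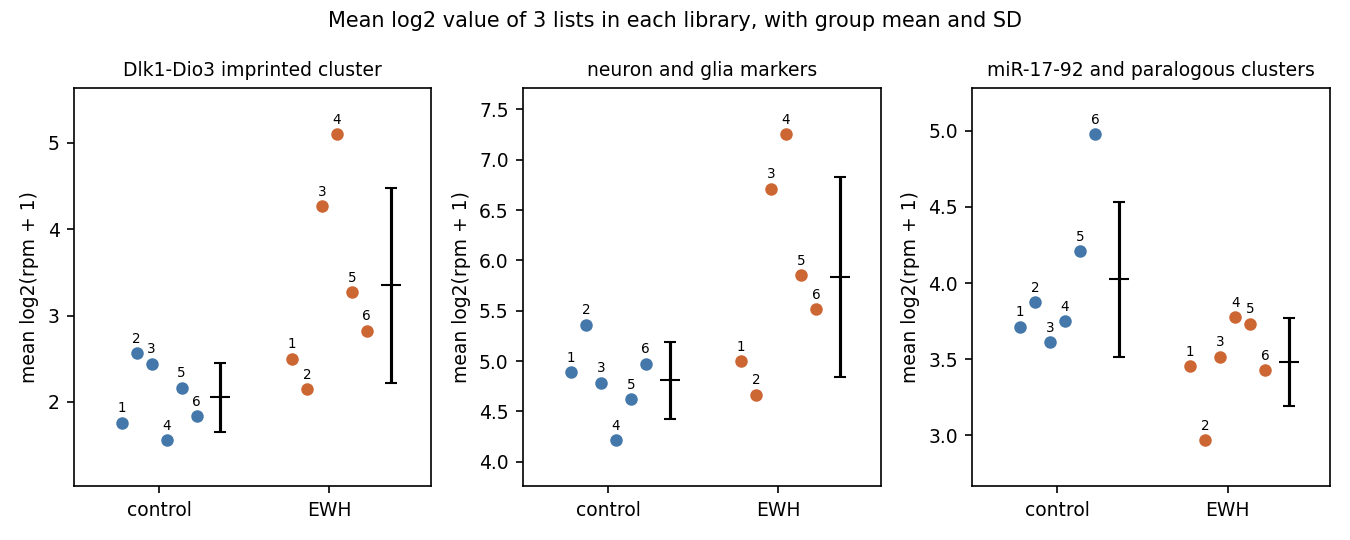
Mean log2(rpm + 1) over the tested members of 3 lists in each library, with replicate numbers beside the points and the group mean with its SD at the right of each group. EWH 4 and EWH 3 stand highest in the Dlk1-Dio3 list (5.10 and 4.26) and in the neuron and glia list (7.26 and 6.71), and control 6 (4.98) stands highest in the miR-17-92 list.

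The miR-17-92 list, which holds this cluster and its paralogs known from cell proliferation, had 9 of 10 tested members lower in EWH and a median log2 fold change of −0.62. Among them miR-93-5p averaged 57.9 ± 28.3 rpm in control and 33.6 ± 6.71 rpm in EWH, miR-106b-3p averaged 38.4 ± 9.77 and 29.2 ± 3.63 rpm, and miR-25-3p averaged 406 ± 61.9 and 371 ± 53.3 rpm (SD, n = 6 each). The member at a higher mean was miR-363-3p, at log2 0.94 (named after its value was seen). None passed limma over all tested miRNAs, 2 passed when adjusted over the list alone, both lower, and edgeR called 2 over all. Camera gave adjusted p = 0.0053 (limma, Benjamini-Hochberg), and adjusted p = 0.672 with an estimated correlation. The count adjusted over the list alone was 0 without control 5 or EWH 1, 3, 4 or 6, 8 lower and 1 higher without control 3, 6 lower without control 4 and 1 lower and 1 higher without EWH 2. It was 0 at a pseudocount of 5 and with no filter on low values, 6 lower and 1 higher under median-of-ratios scaling and 8 lower and 1 higher after quantile normalization. The median was −0.18 with no filter, with 16 of 22 members lower and 6 higher, and −0.38 at a pseudocount of 5. Camera called the list in each of these settings and with each library left out in turn. Its mean log2 value was 4.02 ± 0.51 in control and 3.48 ± 0.29 in EWH (SD, n = 6 each; exact permutation p = 0.0216, adjusted p = 0.104 by Benjamini-Hochberg). Control 6 stood highest in this list and also in the epithelial and hepatocyte list, where it scored 5.61 against 3.73 to 4.82 in the other controls.

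Lists of miRNAs known from proliferating smooth muscle and from limits on fibrosis lay slightly lower in EWH, though the mean log2 values of these lists missed the threshold after adjustment. They were 7.44 ± 0.13 in control and 7.22 ± 0.19 in EWH for the first (SD, n = 6 each; exact permutation p = 0.0368) and 6.37 ± 0.14 and 6.18 ± 0.05 for the second (SD, n = 6 each; exact permutation p = 0.0130, the smallest of the 17 lists). Adjusted p was 0.104 by Benjamini-Hochberg over the 17 lists for both. In the proliferative smooth muscle list 9 of 10 tested members were lower, with a median log2 fold change of −0.26, and 6 of the 10 are also in another list. Its leading members were miR-21-5p at 7380 ± 1503 rpm in control and 5804 ± 836 rpm in EWH, and miR-24-3p at 6270 ± 603 and 5714 ± 535 rpm (SD, n = 6 each). In the miR-29 and antifibrotic list 17 of 19 were lower, with a median of −0.17. It was led by miR-30d-5p at 4038 ± 897 and 3785 ± 207 rpm and miR-30a-5p at 2275 ± 257 and 1961 ± 245 rpm (SD, n = 6 each). Without control 1 the control mean of miR-30d-5p was 3687 rpm, below that of EWH. No member of either list passed limma over all tested miRNAs or when adjusted over the list alone, apart from 1 of the proliferative list over the list alone, without EWH 4 and also with no filter on low values, where the proliferative median was −0.16 with 16 of 20 members lower. Limma's camera gave Benjamini-Hochberg adjusted p = 0.0288 for both, and adjusted p = 0.672 for both with an estimated correlation. Both calls ended without EWH 3 and 4 together (adjusted p = 0.141 and 0.168) and without control 2 (0.097 and 0.082), under limma's camera with Benjamini-Hochberg adjustment, and also for the first without EWH 3 (0.076) and for the second without control 1 (0.070) or EWH 4 (0.092). Both also ended under median-of-ratios scaling (0.051 and 0.056) and quantile normalization (0.158 and 0.225), and the second at a filter of 10 rpm (0.107), by the same test.

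The other 12 lists were not called by limma's camera (Benjamini-Hochberg adjusted p from 0.109 to 0.961), and no list was called with an estimated correlation (smallest adjusted p = 0.672) or by fry (smallest adjusted p = 0.194). No member of the 12 passed limma over all tested miRNAs, and when adjusted over the list alone 1 passed in each of 4 lists (let-7i-5p, miR-27a-5p, miR-9a-5p and miR-1-3p, in that order below) and 0 in the other 8. Exceptions among these 8 were 1 of the contractile list without control 6 or EWH 4 or at a filter of 10 rpm, 1 of the endothelial list after quantile normalization and 1 of the profibrotic list with no filter on low values. With no filter, camera also called the angiotensin, inflammation, hypoxia and profibrotic lists (adjusted p = 0.046 each) and the epithelial list (0.013; limma, Benjamini-Hochberg). By exact permutation of the mean log2 value, the hypoxia list stood at p = 0.0368 (Benjamini-Hochberg adjusted p = 0.104), with 6.11 ± 0.14 in control, 5.86 ± 0.20 in EWH (SD, n = 6 each) and 4 of 6 EWH libraries below each control. Of the 11 tested hypoxia members 6 are also in another list, among them miR-24-3p and miR-146a-5p, both in the proliferative smooth muscle list. Of the 12 tested inflammation members 11 are also in another list. Such lists are not independent observations. The other 11 of these 12 lists had adjusted p from 0.163 to 0.879 in that test. In the let-7 family, inhibitors of proliferation, 10 of 15 tested members, both arms counted, were higher with a median log2 fold change of 0.16. The 5 lower members were let-7g-5p, let-7b-3p, let-7c-1-3p, let-7i-3p and the joint entry of let-7a-1-3p and let-7c-2-3p. The median therefore mixes the 5p forms with 3p arms. Its member let-7c-5p read 22192 ± 5861 rpm in control and 31010 ± 6147 rpm in EWH (SD, n = 6 each). Limma's camera called the list without control 5 (Benjamini-Hochberg adjusted p = 0.039) and at a filter of 10 rpm (0.0061, 10 of 13 higher). The let-7 median was 0.04 with no filter and 0.016 after quantile normalization. Among vessel wall lists, the median was −0.07 for contractile smooth muscle (miR-1b 2497 ± 289 and 2834 ± 744 rpm) and −0.07 for endothelial (miR-126a-3p 5855 ± 3259 and 5214 ± 993 rpm; control then EWH, SD, n = 6 each). Control 1 read 12218 rpm in miR-126a-3p; without it the control mean was 4582 rpm, below that of EWH, and the endothelial median was 0.018. The median was −0.12 for profibrotic (miR-125a-5p 6404 ± 1104 and 6679 ± 709 rpm) (control mean 6711 rpm, above that of EWH, without control 2) and −0.18 for hypoxia and oxidative stress (miR-23a-3p 887 ± 282 and 746 ± 189 rpm; control then EWH, SD, n = 6 each). It was −0.09 for angiotensin and blood pressure, where miR-27a-3p read 7879 ± 1076 and 6623 ± 745 rpm and miR-27a-5p passed when adjusted over the list alone. For inflammation the median was −0.08, where miR-146a-5p read 469 ± 170 and 467 ± 102 rpm and miR-9a-5p passed when adjusted over the list alone (SD, n = 6 each). The inflammation median was 0.017 without control 1 and the angiotensin median 0.0073 without EWH 2, and the order of the miR-146a-5p means turned without control 1 or 3 or EWH 1, 2 or 3. With each library left out in turn, the contractile median ran up to −0.02 (without control 2), the profibrotic median from −0.18 (without control 1) to −0.04 (without EWH 2; −0.06 without control 5) and the hypoxia median up to −0.11 (without EWH 2; −0.12 without EWH 3). The endothelial median ran down to −0.17 (without control 2), the inflammation and angiotensin medians to −0.14 (without control 3 and control 4). Counts adjusted over the list alone were 0 without control 1, 2, 3, 4 or 6 or EWH 3, 4, 5 or 6, after quantile normalization, with no filter or by limma without trend, and 2 without EWH 2 or under median-of-ratios scaling for let-7. They were 0 without control 1, 2, 4, 5 or 6 or EWH 3, 4, 5 or 6 and 2 without EWH 2 for inflammation, with 1 higher and 1 lower with no filter and 2 higher and 1 lower after quantile normalization. For angiotensin and blood pressure they were 2 without control 3 or 4 or EWH 4 and under median-of-ratios scaling or quantile normalization.

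Marker lists of other cells gave medians of 0.01 for erythrocytes (miR-451-5p 43.4 ± 21.2 and 33.1 ± 15.6 rpm) and −0.20 for leukocytes (miR-142-3p 19.8 ± 8.58 and 14.7 ± 3.34 rpm; control then EWH, SD, n = 6 each). The most abundant members of these lists had higher means in EWH, miR-486 at 158 and 162 rpm and miR-146b-5p at 348 and 383 rpm. That order turned without control 1 or 5 or EWH 1 or 5 for miR-486, and without EWH 4 for miR-146b-5p. Medians were −0.29 for adipocytes (miR-148a-3p 60.6 ± 11.7 and 44.9 ± 10.4 rpm), −0.14 for skeletal and cardiac muscle and −0.25 for epithelium and hepatocytes (control then EWH, SD, n = 6 each). Control 1 had the highest mean log2 value of the adipocyte list (5.40, others at most 4.85), and without it the median was 0.020, with 5 members higher and 4 lower. In the muscle list miR-1-3p read 394 ± 238 and 807 ± 273 rpm and miR-499-5p 262 ± 133 and 157 ± 29.1 rpm, and miR-1-3p was its 1 member to pass when adjusted over the list alone, which it did not without control 1 or 3 or EWH 1 or 3; 1 more passed, lower, without control 2 and 2 more, lower, after quantile normalization. The hepatocyte miRNA miR-122-5p read 342 ± 365 and 416 ± 275 rpm (SD, n = 6 each), with a control mean of 209 rpm without control 6 and an EWH mean of 339 rpm, below control, without EWH 6. Median and mean differed in sign for the inflammation list (mean 0.09), the contractile list (mean 0.04), the erythrocyte list (mean −0.06) and the muscle list (mean 0.11); camera's direction was down for the first 3 and up for the muscle list. The erythrocyte median was −0.03 at a pseudocount of 5 and −0.11 after quantile normalization. It was −0.29 without control 1, −0.18 without control 5 or EWH 1 and −0.16 without EWH 5, and 0 of 4 members were higher in each of these and after quantile normalization. It lay at up to 0.18 (without control 4) with other libraries left out. The leukocyte median was −0.08 without control 1 or 2, −0.11 without control 3 and −0.12 without EWH 1. The adipocyte median reached −0.50 without control 4 and was −0.06 without EWH 5 and −0.09 without control 3. The epithelial median was −0.17 without control 5. The muscle median was −0.26 without control 1, −0.02 without control 2 and 0.34 at a filter of 10 rpm. Without control 1 and EWH 3 and 4 together, chosen after seeing the data, the erythrocyte median was −0.06, the muscle median 0.03 and the adipocyte median 0.00016.

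**Figure D3:**
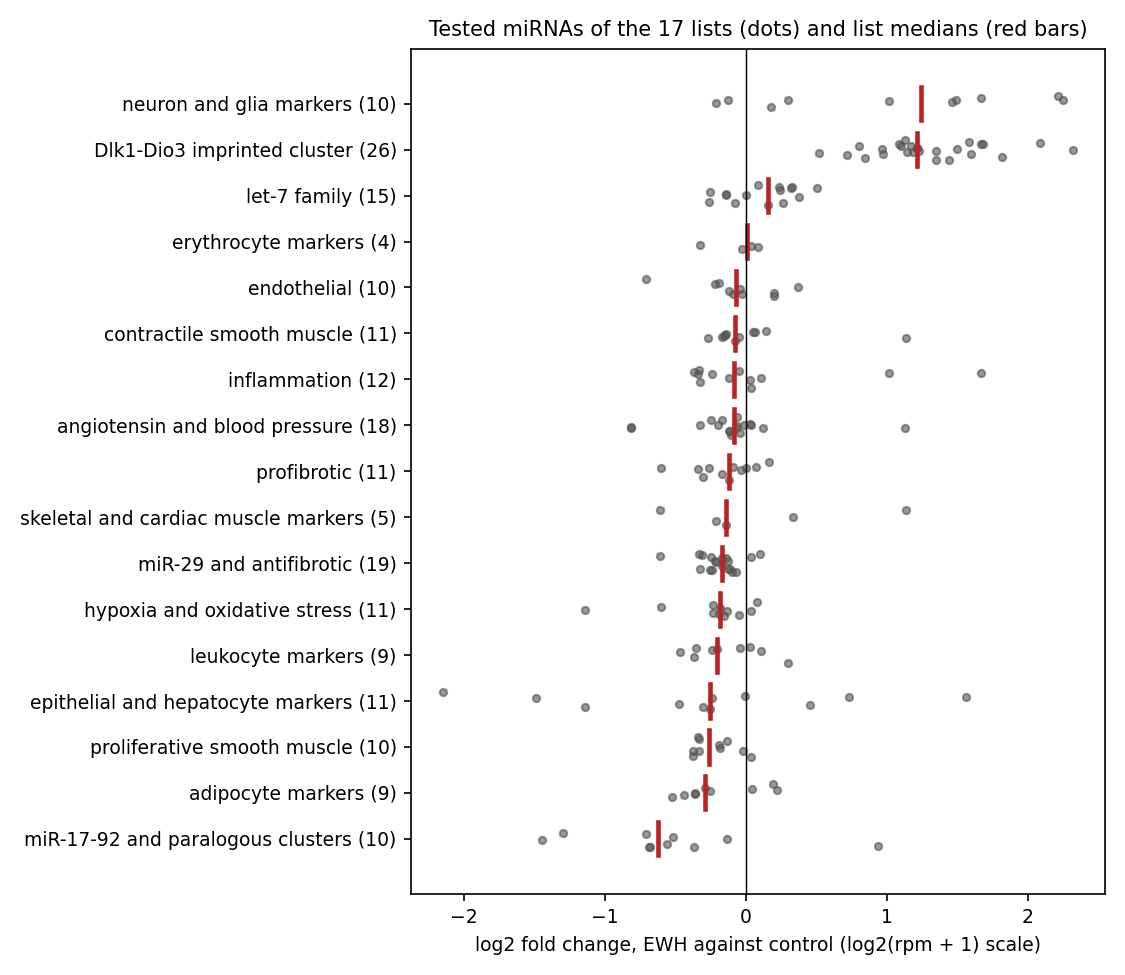
Log2 fold change (EWH against control, log2(rpm + 1) scale) of the tested miRNAs in each of 17 lists, 1 dot per miRNA and a red bar at the list's median, with the number tested in brackets. All 26 members of the Dlk1-Dio3 list lie above 0 with a median of 1.22, and 9 of 10 in the miR-17-92 list lie below 0 with a median of −0.62.

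The balance between the 2 arms of a hairpin depends little on library scaling, and 67 hairpins had both arms tested. The largest shifts by p were in let-7i, where the log2 ratio of 5p over 3p was 12.04 ± 0.29 in control and 12.54 ± 0.17 in EWH, miR-27a, at −7.42 ± 0.30 and −7.99 ± 0.38, and miR-9a, at 3.62 ± 0.54 and 4.28 ± 0.28 (SD, n = 6 each). None passed limma, with Benjamini-Hochberg adjusted p of 0.091, 0.165 and 0.165, and 13 hairpins had an unadjusted limma p under 0.05. The let-7i ratio passed without control 4 (adjusted p = 0.047) or control 5 (0.018), and the miR-27a ratio without EWH 4 (0.045), by limma with Benjamini-Hochberg adjustment. At a pseudocount of 5 in place of 1, 3 ratios passed.

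As whole profiles of the 303 tested miRNAs the groups differed by more than most other splits of the libraries. Group accounted for 24.7% of the variation in a permutational analysis of variance (exact permutation p = 0.0108, where 0.00216 is the smallest possible). That p is the share of the 924 splits whose group accounted for at least as much. Without EWH 3 and 4 together the profile separation, EWH against control, was a fraction of 0.171 in place of 0.247 and no longer passed (exact permutation p = 0.124), while it passed with each single library left out in turn.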

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

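The tests of technical explanations in this part (nerve tissue, EWH 3 and 4 alone, depth, another tissue, aortic segment, control 6 alone, epithelial cells) were chosen after the results were seen, those for nerve tissue, another tissue, segment and epithelial cells being made stricter after a first outcome, and the counts over other splits before.

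Among 100 of the 462 ways to split the 12 libraries 6 against 6, the real one included, 1 of 100 gave as many edgeR calls as the real 40 (highest other 7). There were 1 of 100 with as many DESeq2 calls as the real 63 (highest other 45) and 1 of 100 with as many unadjusted limma p under 0.05 as the real 70 (highest other 52). None of the other drawn splits reached these 3 counts, which makes chance unlikely for them. It is not excluded, since not all 462 splits were drawn and samples of a group may not be separate animals. For the 5 lists called by camera, 11 of 100 splits gave as many (highest other 6), so chance cannot be excluded. For the 0 miRNAs and the 0 arm ratios called by limma (unadjusted 70 and 13), 100 of 100 splits gave as many, the highest others being 1 and 2. Since no count can lie below 0, that share was fixed in advance and decides nothing.

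The Dlk1-Dio3 and neuron and glia lists, which share 0 tested members, stood higher in EWH, most in EWH 3 and 4. Nerve tissue dissected with some aortas may carry both: across the EWH libraries their mean log2 values went together (Pearson r 0.993, exact permutation p = 0.00139, adjusted p = 0.00556 over 4 relations by Benjamini-Hochberg; rho 1, p = 0.00278; r 0.991 without the 2 farthest libraries). Across the controls r was 0.633 (exact permutation p = 0.183; rho 0.543, p = 0.297), rested on 2 libraries (−0.63 without them) and does not decide it; miR-124-3p, abundant in neurons, stood highest in EWH 3 and 4 too, at a low 3.30 and 4.98 rpm (others at most 0.997), as did miR-137-3p at 1.51 and 2.18 rpm (others at most 0.415). Whether EWH 3 and 4 alone make the difference cannot be told apart either: without them 25 of 26 Dlk1-Dio3 members still had higher means and the list's mean log2 value differed by 0.63 (exact permutation p = 0.0667), while 6 of 10 neuron and glia members did and that list differed by 0.45 (p = 0.162). The treatment itself stays open as untested.

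Control 1 was low in 3 miR-196 5p forms, whose hairpins lie in Hox clusters: miR-196a-5p 10.2 rpm against 317 to 562 in the other 11 libraries, miR-196b-5p 50.9 against 356 to 494 and miR-196c-5p 0.244 against 1.69 to 3.77. The tables argue against lower depth, its total of 24617270 reads lying within 23887799 to 24772944. Another tissue in place of aorta, or mixed with it, cannot be told apart: miR-143-3p, which muscular tissues share, held 45.2% of listed reads, within 42.3% to 54.1% in the others, while control 1 had the lowest mean log2 value of the contractile list (9.55, others 9.63 to 9.89) and the highest of the adipocyte list (5.40, others 3.82 to 4.85), and 4 miRNAs lay below and 13 above all other libraries by over 2-fold. Another segment of the aorta may differ in Hox-linked miRNAs, but this stays open too, since miR-10a-5p (23366 rpm) lay within the others' 14813 to 26385 while miR-10b-5p (4.67 rpm) lay below their 5.89 to 12.1. The low miR-615, whose hairpin lies inside Hoxc6 and Hoxc5, also lay below the others, at 0.650 rpm against 1.14 to 2.80. No biological explanation was tested, as the design gives none within a group.

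The miR-17-92 list stood lower in EWH, with controls 6 and 5 highest. The tables argue against control 6 alone as the whole cause, since without it the list's mean log2 value still differed by −0.35 in place of −0.54. The exact permutation p = 0.039 for this was not adjusted over the 17 lists, and with all libraries the adjusted p was 0.104 (Benjamini-Hochberg). Without controls 5 and 6 the difference was −0.26 (exact permutation p = 0.119), and without controls 4 to 6 also −0.26 (p = 0.214). Epithelial cells in some control samples may raise it, and across the controls it went with the epithelial and hepatocyte list (r 0.925, exact permutation p = 0.0167, adjusted p = 0.0333 over 4 relations by Benjamini-Hochberg; rho 0.714, p = 0.136), but without the 2 farthest libraries r was −0.03, so the relation rests on those and the explanation cannot be told apart. In EWH r was 0.768 (exact permutation p = 0.0583; rho 0.771, p = 0.103; r 0.957 without 2). The treatment stays open as untested.

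In 9 of 178 groups of 6 libraries examined, 1 library lay far from the others by Dixon's criterion (gap over range above the 95% critical value), about the 1 in 20 that chance gives; control 6 was that library in 3 and EWH 2 in 2. In log2(rpm + 1), control 6 read 5.88 in miR-106b-3p (other controls 5.0 to 5.27), 9.05 in miR-25-3p (8.51 to 8.65) and 10.92 in miR-1b (11.28 to 11.43). EWH 2 read 12.37 in miR-125a-5p (other EWH 12.72 to 12.84) and 11.67 in miR-22-3p (11.98 to 12.13), and EWH 4 read 5.07 in miR-31a-5p (4.45 to 4.57). Control 2 read 9.75 in miR-140-3p (other controls 9.10 to 9.32), control 1 read 12.50 in miR-30d-5p (11.64 to 11.93) and control 3 read 15.30 in miR-99a-5p (15.00 to 15.10).

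Among the 338 miRNAs too low to be tested, 1 had each EWH library above each control and 1 had each below, where chance gives 0.108% of miRNAs, or 0.366 of the 338, in each direction. Picked for this, miR-758-3p of the Dlk1-Dio3 list averaged 0.889 rpm in EWH, or 0.565 rpm without EWH 4 (2.51 rpm), with controls at 0 to 0.167 rpm. MiR-21-3p lay at 0.161 to 0.377 rpm in EWH and 0.411 to 1.61 rpm in control.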

How the results depend on the processing

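Fits without several libraries together and edgeR fits with a library left out were chosen after seeing the data, and the other alternatives before. Limma called 0 miRNAs under each filter, pseudocount, variance model and median-of-ratios scaling, 8 after quantile normalization, 0 to 24 with a library left out, 1 without EWH replicates 3 and 4 together and 1 without these and control replicate 1. EdgeR called 40 and DESeq2 63. With a library left out edgeR called 0 without control 1, 4, 5 or 6 or EWH 3 or 4, 33 without control 2, 37 without control 3, 45 without EWH 1, 44 without EWH 2, 27 without EWH 5 and 31 without EWH 6. Of unadjusted limma calls 65.7% were higher, against 53.8% after quantile normalization, 54.1% at a filter of 10 rpm, 56.1% to 81.5% with a library left out, 50% (19 higher, 19 lower) without EWH 3 and 4 and 41.7% (15 higher, 21 lower) without control 1 too. The 5 lists called by camera were 10 with no filter on low values, 3 under median-of-ratios scaling, 3 after quantile normalization, 3 to 6 with a library left out, 3 without EWH 3 and 4 together and 3 without these and control 1. They were 0 with an estimated correlation and 0 by fry. The Dlk1-Dio3, neuron and glia and miR-17-92 lists were among those called in all settings but these 2. The 0 arm ratios were 3 at a pseudocount of 5, 0 to 1 with a library left out and 1 without control 1 and EWH 3 and 4. The profile separation, EWH against control, as a fraction, was 0.171 without EWH 3 and 4 (exact permutation p = 0.124), 0.216 without control 1 too (p = 0.079) and 0.204 to 0.310 with a library left out. The difference in number of miRNAs at 1 rpm was −1.33 without EWH 3 and 4 and −2.5 without control 1 too; that in median log2 was −0.12 and −0.020, and −0.047 to 0.14 with a library left out. The replicate number as a block gave 0 miRNAs (57 unadjusted), 6 lists and a profile share of 0.370 (exact permutation p = 0.0625). It called let-7 by camera (limma, Benjamini-Hochberg adjusted p = 0.023), with 5 members adjusted over the list alone, and 0 members of each other list. The values did not show a pairing by number: deviations of same-numbered libraries correlated from −0.50 to 0.31, 3 of 6 above 0.1. Only 1 of 12 libraries correlated best with its own number. With 6 such correlations a pairing cannot be excluded, and the labels do not say whether there was one. Quantile normalization fixes the composition measures and gives no value for them. Beyond these, 1961 values kept direction and side of the threshold, 70 passed newly, 28 no longer passed and 71 called in neither setting changed direction (for lists, camera's); no called value did. The median also changed sign in at least 1 setting for the adipocyte, endothelial, inflammation, angiotensin, erythrocyte and muscle lists, none called there. Unless fewer miRNAs or libraries explain a change, the cause was not tested. Depth limits miRNAs near the floor of 0.121 to 0.126 rpm.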

Other observations

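The miRNAs in this part were chosen after their values were seen, and no test beyond the group comparison was run on them; in that, limma called none, and of those named edgeR called miR-7b, miR-200a-3p and miR-200b-3p (Benjamini-Hochberg adjusted p = 0.031, 0.046 and 0.033). Within the EWH group, EWH 3 and EWH 4 were apart in, among others, 2 miRNAs of the neuron and glia list and 1 of the epithelial and hepatocyte list. Of the former, miR-7b read 41.0 and 135 rpm there against at most 6.10 rpm in the other 10 libraries and miR-129-5p 121 and 167 rpm against at most 41.9; of the latter, miR-375-3p read 62.0 and 206 rpm against at most 10.8. MiR-128-3p, the most abundant of the neuron and glia list, did not set them apart, at 619 and 825 rpm against 495 to 1203 rpm elsewhere. Of 56 Dlk1-Dio3 miRNAs too low to be tested, 52 had a higher mean in EWH.

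Members of the epithelial and hepatocyte list stood highest in different libraries. In controls 4, 5 and 6 miR-200b-3p read 58.6, 176 and 501 rpm against at most 10.2 rpm in the other 9 libraries, and miR-200a-3p 18.5, 46.6 and 94.7 rpm against at most 8.81, while miR-429, of the same cluster, lay at 1.17 to 3.42 rpm in all 12. Among these 3 controls miR-200c-3p reached 24.7 rpm against at most 2.35 elsewhere. There miR-141-3p, too low to be tested, reached 11.9 rpm against at most 0.334 elsewhere. MiR-375-3p and miR-205 (29.2 rpm) were highest in EWH 4, whose mean log2 value of the list (4.65) lay above that of control 4 (4.37). Control 6 was highest in miR-182 (54.1 rpm), miR-183-5p (30.9 rpm) and miR-192-5p (308 rpm). Control 1 was highest in miR-378a-3p (1321 rpm, others at most 489), miR-3557-5p (13504 rpm, others at most 4001), miR-203a-3p (572 rpm, others at most 209) and the endothelial miR-126a-3p (12218 rpm, others at most 6858). The hairpins of miR-378a and miR-3557 overlap, so these need not be separate traits. MiRNAs over 2-fold outside all other libraries numbered 4 below and 13 above in control 1, 9 above in control 6, 9 above in EWH 4, 1 above in control 2 and 0 in the other 8.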
